A study of Mus musculus with 10 samples.

How the data were processed

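RNA was measured in 10 libraries of 3T3-L1 cells that carried a control shRNA, 1 of 2 shRNAs against Ddx50 or 1 of 2 shRNAs against Stau1. Per the labels, RNA was extracted with an RNeasy Plus kit and libraries were made with a QuantSeq 3' mRNA kit of the forward type and its UMI module, then sequenced on a NovaSeq X Plus. This chemistry reads the 3' ends of polyadenylated RNA, so a count does not grow with transcript length.

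The values are whole-number counts per gene, deposited by the authors in 1 table with 1 column per library and no normalization. Per the submitters' processing notes, STAR 2.7, featureCounts and DESeq2 1.38.3 were used with the GRCm39 genome; the notes give no role or setting for any of them. Whether reads were collapsed by UMI, which strand setting was used and which annotation release was counted is not given in the sources used here. Without collapsed UMIs, copies made by PCR add spread to the counts. Without a stated strand setting, reads of a gene and of an antisense partner cannot be told apart.

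The table held 56953 genes, of which 52029 identifiers were paired with a symbol through the mouse GENCODE M21 annotation, which was used for names only; 66 symbols carried by several identifiers were kept for 1 of them. Coordinates are those of the deposited table, on GRCm39. Every count column matched 1 library by its label, and 0 columns were left over. Library totals ran from 8693588 to 14117743 counts.

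Counts were tested with edgeR 4.0.16 (R 4.3.3). Genes with low counts were removed with filterByExpr, which left 12571 genes holding 99.8 to 99.9% of the counts of each library. Library sizes were scaled with TMM factors of 0.911 to 1.18. CPM values use these scaled sizes. A quasi-likelihood model with robust dispersion was fitted to all 5 groups together, with 5 residual degrees of freedom, a common biological coefficient of variation of 0.435 and no covariate. A knockdown was the mean of its 2 shRNA groups. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. All gene-level adjusted p-values come from this fit unless another tool is named.

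Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it; fry asks whether a list's genes move one way on balance and does not compare them with other genes. The 28 lists held 616 genes, of which 1 had no match in the table and 7 were matched through synonyms. They covered adipocyte markers, adipogenic transcription factors, fatty acid synthesis, triglyceride synthesis and lipid droplets, lipolysis and fatty acid oxidation, cholesterol synthesis, insulin signalling and adipokines, oxidative phosphorylation, thermogenic adipocyte genes, preadipocyte and fibroblast markers, extracellular matrix, contractile and myofibroblast genes, cell cycle, interferon-stimulated genes, inflammatory cytokines and NF-kB targets, p53 targets, the integrated stress response, ER chaperones, rRNA processing, cytosolic ribosomal proteins, nonsense- and Staufen-mediated decay factors, immediate early genes, the glucocorticoid response, hypoxia and glycolysis, and bone and cartilage, macrophage, skeletal muscle and endothelial markers. At least 3 tested members were required, which 25 lists had. Lists overlap: 11 of the 17 tested adipocyte markers are also in another list, against 1 of the 17 tested preadipocyte markers. Per-library list means on the log2 CPM scale were compared with exact two-sided permutation tests.

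Named genes followed a rule: the targets and their paralogs Ddx21 and Stau2; the genes with the largest change among those past the threshold, with at least 10 CPM and no overlap between groups; Pparg, Cebpa, Fabp4, Adipoq and Plin1; and, for each list past the threshold and for the adipocyte and preadipocyte lists, the 4 tested members with the smallest p. The rule gave 70 genes for STAU1 against control, 35 for DDX50 against control and 52 for DDX50 against STAU1. Groups, tests, lists, this rule and most alternatives were set before the data were examined.

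The labels call the 2 libraries of a group biological replicates without saying which step was repeated. P-values therefore measure the spread between these libraries. Counts of paired libraries differed by far more than sampling noise, with a chi-square per degree of freedom of 58.0 to 145 in the 5 pairs within groups, and each library was counted as 1 sample. Copies from amplification would raise these values, and libraries of different groups were not compared in this way.

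Genes with near-identical copies are uncertain, because reads shared between copies may have been dropped or split. Gapdh had 2.68 to 21.1 CPM, Ppia 1.77 to 10.9, Rps2 3.64 to 17.7 and Rpl3 6.20 to 22.4, while Actb had 4416 to 9286. Ribosomal protein genes share this limit, and Gapdh is in the hypoxia and glycolysis list.

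Alternatives were other scaling factors, other low-count filters, DESeq2 1.42.0, the replicate number as a block, fits of the groups compared alone, 3 groups by target, and each library left out in turn. Leaving out a library leaves its group with 1, whose spread is then taken from the other groups. Overlap and correlation of the knockdowns were set beside 20 simulations of unchanged groups against shared control libraries. The correlation was also taken with 1 control library for each knockdown and none shared, on log2 CPM values, and with 1 library shared by both.

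The tests were also run on simulated counts for the same 12571 genes, with 200 changed. These counts were drawn from means and dispersions fitted to the real data. For STAU1 against control, 1% of genes changed 2-fold, 77.5% of those changed 4-fold and 98% of those changed 8-fold were recovered, with 0, 8 and 14 unchanged genes called. For DDX50 against control the shares were 0, 74 and 98%, with 0, 13 and 11 unchanged genes called. For DDX50 against STAU1 they were 3.5, 92 and 100%, with 0, 21 and 8. A 2-fold lowering of the adipocyte list gave a camera adjusted p of 7.46e-14, 1.09e-11 and 1.23e-24 in these comparisons, and 0 of 20 lists without shared members were called. Simulated genes were drawn independently of each other, here and in the simulations of unchanged groups. The 0 of 20 therefore does not measure how often camera calls unchanged lists when genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.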

Results

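The data describe 3T3-L1 cells, a mouse preadipocyte line, in the adipocyte state named by the labels, after induction in medium with 10% fetal bovine serum, insulin at 10 µg/mL, dexamethasone at 1 µM and the phosphodiesterase inhibitor IBMX at 0.5 mM. Cells carried a control shRNA, DDX50_sh1 or DDX50_sh2 against Ddx50, or STAU1_sh2 or STAU1_sh4 against Stau1, with 2 libraries in each of the 5 groups. DDX50 is a DEAD-box RNA helicase and STAU1 a double-stranded RNA-binding protein. The question named by the series title is whether the 2 proteins act together on RNAs that favour differentiation. The 3' ends of polyadenylated RNA were counted per gene, with 8693588 to 14117743 counts per library.

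Each target transcript was lowest in the libraries labelled for its own shRNAs. Ddx50 (ENSMUSG00000020076.8, GRCm39 chromosome 10, 62451794 to 62486997) averaged 11.8 ± 0.868 CPM (SD, n = 4) with the DDX50 shRNAs against 44.4 ± 18.0 (n = 2) in control, 3.74-fold lower. Stau1 (ENSMUSG00000039536.17, chromosome 2, 166789469 to 166838219) averaged 6.38 ± 2.13 CPM (n = 4) with the STAU1 shRNAs against 32.6 ± 12.7 in control, 5.19-fold lower. Both shRNAs of a target gave similar values, with log2 fold changes of Ddx50 of -1.90 and -1.91 and of Stau1 of -2.13 and -2.63. In neither case did the knockdown libraries overlap the control libraries. Neither fold passed the threshold over 12571 genes, with an adjusted p of 0.968 for Ddx50 (unadjusted p = 9.13e-05) and 0.0506 for Stau1 (unadjusted p = 2.82e-05). Stau1 passed it in the direct test of DDX50 against STAU1 (log2 fold change 2.60, SE 0.331, adjusted p = 0.0476), where Ddx50 had a log2 fold change of -1.48 (adjusted p = 0.107). Ddx50 with the STAU1 shRNAs was at 33.3 ± 7.73 CPM (log2 fold change -0.43, SE 0.342, adjusted p = 0.692), and 0.04 without control replicate 1. Stau1 with the DDX50 shRNAs was at 37.9 ± 7.29 CPM (log2 fold change 0.22, SE 0.380, adjusted p = 0.981), and -0.12 without control replicate 2. The paralog Ddx21 was at 1433 ± 457 CPM in control, 1203 ± 343 with the DDX50 shRNAs and 1490 ± 840 with the STAU1 shRNAs. Stau2, the paralog of Stau1, was at 2.75 ± 0.610, 3.51 ± 1.43 and 2.06 ± 1.46 CPM.

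**Figure D1:**
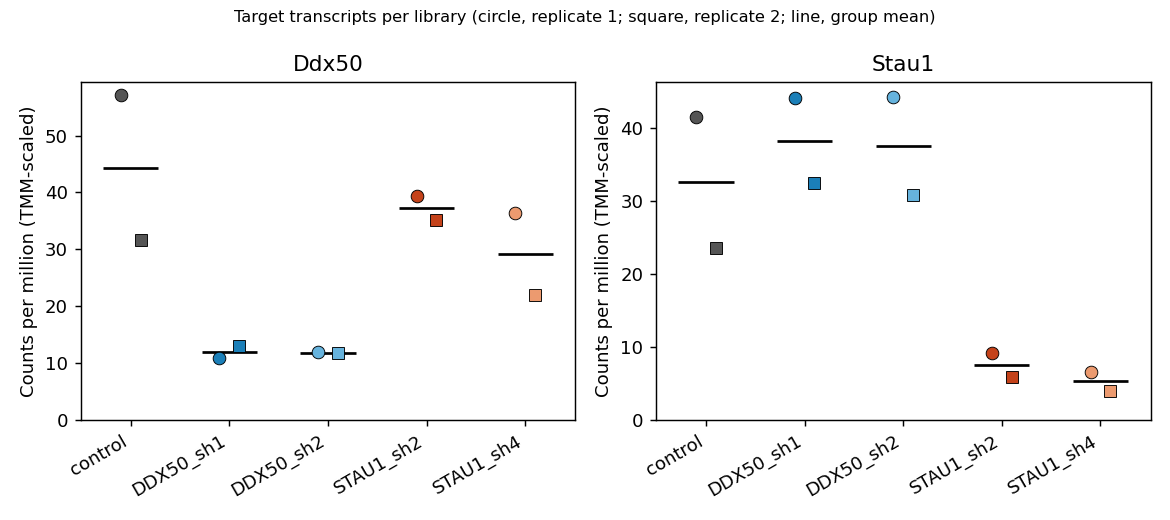
TMM-scaled CPM of Ddx50 (left) and Stau1 (right) in each library by group, with circles for replicate 1, squares for replicate 2 and a line at the group mean. Ddx50 lies between 10.8 and 12.9 in the 4 DDX50 shRNA libraries and Stau1 between 3.95 and 9.10 in the 4 STAU1 shRNA libraries, below both control libraries of each gene.

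Knockdown of STAU1 against control asked which RNAs of the differentiated cells depend on STAU1. Adipocyte markers fell as a group, with all 17 tested members lower and a median log2 fold change of -2.38. Adipoq, which encodes the adipokine adiponectin (chromosome 16, 22965286 to 22976778), averaged 35.5 ± 14.9 CPM (SD, n = 4) against 160 ± 148 (n = 2) in control, where the 2 libraries had 54.97 and 264. The log2 fold change of Adipoq was -2.25, but -0.70 without control replicate 2 and larger in size without control replicate 1, and the highest STAU1 library had 54.69 CPM. Fabp4, a fatty acid carrier (chromosome 3, 10269148 to 10273636), averaged 199 ± 201 against 959 ± 27.5 CPM, and Plin1, a coat protein of lipid droplets (chromosome 7, 79369966 to 79382651), 20.04 ± 13.8 against 115 ± 36.9. With the STAU1 shRNAs Fabp4 was at 243 and 465 CPM in replicate 1 and at 32.5 and 56.3 in replicate 2. Against the control library of the same number, the log2 mean of the 17 markers differed by -1.38 in replicate 1 and -3.20 in replicate 2. Pparg, the nuclear receptor that drives adipogenesis (chromosome 6, 115337912 to 115467360), averaged 9.18 ± 5.10 against 26.5 ± 3.16 CPM, and its partner Cebpa 56.0 ± 22.5 against 119 ± 5.28. Cidec, Retn, Cfd and Slc2a4, the insulin-responsive glucose transporter, had log2 fold changes of -2.98, -3.16, -3.07 and -2.90. Of the 17 markers, 17 were lower at an adjusted p under 0.05 adjusted over the list alone and 0 over all genes tested. The camera adjusted p of the list was 3.88e-24, and the adjusted p was 0.0431 with an estimated correlation. The list mean per library was 4.00 to 5.90 on the log2 CPM scale with the STAU1 shRNAs and 6.91 and 7.50 in control. This difference of -2.29 had an exact two-sided permutation p of 0.0667, the smallest that 4 against 2 libraries can give, and 0.185 after Benjamini-Hochberg adjustment over 25 lists. In the same libraries, 14 of 17 tested preadipocyte and fibroblast markers were higher.

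Genes of lipid storage and lipid use fell together with the adipocyte markers. Scd1, the main fatty acid desaturase of adipocytes (chromosome 19, 44382894 to 44396148), averaged 252 ± 133 CPM (SD, n = 4) against 1831 ± 201 (n = 2), a 7.30-fold lower value (log2 fold change -2.87, SE 0.427, adjusted p = 0.0503). Agpat2, an acyltransferase of triglyceride synthesis (chromosome 2, 26483069 to 26494344), averaged 22.9 ± 8.99 against 111 ± 8.89 CPM, 4.99-fold lower (adjusted p = 0.0503). Of 16 tested genes of triglyceride synthesis and lipid droplets, 14 were lower and 10 passed the threshold adjusted over the list alone, among them Lpin1 (log2 fold change -1.78) and Dgat2 (-2.58). The camera adjusted p of this list was 2.98e-12, and the adjusted p was 0.0431 with an estimated correlation. Fatty acid synthesis had 14 of 18 genes lower and 6 past the threshold adjusted over the list alone, with Thrsp at -3.31, Scd2 at -1.34 and the citrate carrier Slc25a1 at -1.54 (camera adjusted p = 1.06e-05; adjusted p = 0.0430 with an estimated correlation). Lipolysis and fatty acid oxidation had 16 of 19 lower and 11 past it, with Acadm at -1.29, Acadl at -1.12, Hadh at -1.75 and the triglyceride lipase Pnpla2 at -1.47 (camera adjusted p = 2.90e-10; adjusted p = 0.0430 with an estimated correlation). Insulin signalling and adipokines had 15 of 16 lower and 7 past it (camera adjusted p = 8.96e-09; adjusted p = 0.0430 with an estimated correlation). None of these genes passed the threshold over all genes tested. These 4 calls, and that of adipocyte markers, held without any single library.

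Further lists had lower values with the STAU1 shRNAs, and the 6 given here lost their calls with an estimated correlation. Adipogenic transcription factors fell, with 13 of 19 lower, and 5 passed the threshold adjusted over the list alone, among them Ppargc1b at a log2 fold change of -1.81 and Zfp423 at -1.13 (camera adjusted p = 0.00266; adjusted p = 0.0748 with an estimated correlation). Cholesterol synthesis fell, with 20 of 23 lower and 5 past it, among them Cyp51 at -1.77, Insig1 at -1.77, Hmgcs1 at -1.51 and Msmo1 at -1.04 (camera adjusted p = 8.32e-06; adjusted p = 0.140 with an estimated correlation). ER chaperones fell, with 19 of 20 lower and 0 past it; the disulfide isomerases Pdia4 and Pdia6 were at -1.01 and -0.93 (camera adjusted p = 1.01e-05; adjusted p = 0.0941 with an estimated correlation). Hypoxia and glycolysis genes fell, with 17 of 24 lower and 2 past it, Hk2 at -1.39 and Pfkl at -1.05 (camera adjusted p = 0.00205, and 0.280 with an estimated correlation). Their list mean differed from control by -0.65 in replicate 1 and by -0.014 in replicate 2 (exact two-sided permutation p = 0.267 over all libraries compared). Oxidative phosphorylation fell by a median of 0.30 on the log2 scale, with 22 of 32 lower, 0 past that threshold and Cyc1 at -0.96 (camera adjusted p = 0.000625, and 0.301 with an estimated correlation). Its list mean differed from control by -0.58 with STAU1_sh2 and -0.14 with STAU1_sh4 (exact two-sided permutation p = 0.333 over both). STAU1_sh4 replicate 1, at 5.59, lay above both control libraries, at 5.56 and 5.58. Thermogenic genes had 5 of 5 lower, 0 past the threshold adjusted over the list alone and Cox7a1 at -1.91 (camera adjusted p = 0.0210, and 0.141 with an estimated correlation). Without control replicate 2 the calls of transcription factors (camera adjusted p = 0.0856), cholesterol synthesis (0.0727), ER chaperones (0.0658) and thermogenic genes (0.282) ended, and without control replicate 1 that of hypoxia and glycolysis (0.232). The thermogenic call also ended without DDX50_sh2 replicate 2 (0.0570), STAU1_sh2 replicate 1 (0.0558) or STAU1_sh4 replicate 1 (0.0875).

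Markers of undifferentiated and contractile fibroblasts rose with the STAU1 shRNAs by the list test. Preadipocyte and fibroblast markers had 14 of 17 higher, a median log2 fold change of 1.10, and 3 genes past the threshold adjusted over the list alone: Twist2 at 1.10, Sox9 at 1.45 and Pi16, a marker of fibroblast progenitors, at 1.98 (camera adjusted p = 7.41e-06; adjusted p = 0.140 with an estimated correlation). Contractile and myofibroblast genes had 15 of 18 higher and 4 past it, with smooth muscle actin Acta2 at 3.34 (153 ± 184 CPM against 13.5 ± 4.83), Actg2 at 5.74 from a near-zero control level, Cnn2 at 1.83 and Actn1 at 1.16 (camera adjusted p = 1.06e-05; adjusted p = 0.229 with an estimated correlation). Extracellular matrix genes had 20 of 30 higher; the metalloprotease Mmp14 (1.37), the inhibitor Timp2 (1.79) and fibrillin Fbn1 (1.36) were among 4 higher past it, and decorin Dcn (-1.08) was the 1 lower (camera adjusted p = 0.0112; adjusted p = 0.349 with an estimated correlation). The matrix call ended without STAU1_sh4 replicate 2 (camera adjusted p = 0.0971). In STAU1_sh4 replicate 1 the list mean was 3.20 for contractile genes, against 3.19 and 3.11 in control, and 6.85 for matrix genes, below the control values of 7.01 and 6.96. Exact two-sided permutation p-values of the list means were 0.133 for preadipocyte markers, 0.133 for contractile genes and 0.333 for matrix genes, and 0.278, 0.278 and 0.490 after Benjamini-Hochberg adjustment over 25 lists.

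Interferon-stimulated genes, p53 targets and ribosomal protein genes also rose by the list test, with 0 members past the threshold adjusted over the list alone. Interferon-stimulated genes had 11 of 13 higher at low levels, such as Bst2 at 5.99 ± 3.67 CPM (SD, n = 4) against 1.21 ± 0.720 (n = 2) and Isg15 at 1.70 ± 1.15 against 0.351 ± 0.0743 (camera adjusted p = 0.0106; adjusted p = 0.229 with an estimated correlation). The p53 targets had 19 of 25 higher, with Bax at a log2 fold change of 0.72 but Mdm2 at -0.60 and Rrm2b at -1.36 (camera adjusted p = 0.0493; adjusted p = 0.457 with an estimated correlation). Ribosomal protein genes had 33 of 43 higher, with Rps20 at 0.71 and Rpl4 at 0.68 (camera adjusted p = 0.00456; adjusted p = 0.452 with an estimated correlation). The ribosomal rise lay in STAU1_sh4, with 37 of 43 higher (median log2 fold change 0.77, camera adjusted p = 1.48e-07; adjusted p = 0.227 with an estimated correlation), while with STAU1_sh2 21 of 43 were higher (-0.02, camera adjusted p = 0.832) and its list means, 7.22 and 6.92, lay between those of control, 7.27 and 6.83. The p53 list was called with neither STAU1 shRNA alone (camera adjusted p = 0.0761 and 0.119). The interferon call ended without control replicate 1 (camera adjusted p = 0.0702), STAU1_sh2 replicate 2 (0.0692) or STAU1_sh4 replicate 2 (0.0690), and with a stricter low-count filter (0.139). The p53 call turned direction without control replicate 1 (0.813) and ended without DDX50_sh1 replicate 2 (0.05005), STAU1_sh2 replicate 2 (0.231) or STAU1_sh4 replicate 2 (0.0924), and with the stricter filter (0.150). The ribosomal call ended without control replicate 2 (0.368) or STAU1_sh2 replicate 1 (0.0871).

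Cell cycle genes (median log2 fold change -0.03, camera adjusted p = 0.845), inflammatory cytokines and NF-kB targets (0.13, 0.569), the integrated stress response (0.19, 0.609), rRNA processing (-0.09, 0.140), nonsense- and Staufen-mediated decay factors (-0.09, 0.254), immediate early genes (0.44, 0.254) and glucocorticoid response genes (0.02, 0.799) were not called in STAU1 against control. Bone and cartilage markers were not called either (camera adjusted p = 0.844); their median was -0.20 while the test pointed up, and Sox9 passed the threshold adjusted over the list alone. Macrophage and skeletal muscle markers had 2 tested members each and endothelial markers 1, so these lists were not tested. Their highest members were Cd68 at 3.25 CPM, Des at 5.27 and Egfl7 at 62.1. Gene by gene, edgeR called 0 of 12571 genes, although 1360 had an unadjusted p under 0.05, 593 higher and 767 lower. Chance alone would give 629. With the replicate number as a block edgeR called 42, 2 higher and 40 lower. Of these, 4 are adipocyte markers and 10 belong to the 7 adipocyte and lipid lists. DESeq2 called 217, 82 higher and 135 lower, of which 12 are adipocyte markers and 29 belong to the 7 adipocyte and lipid lists. The edgeR count was 106 without STAU1_sh4 replicate 1, 10 without DDX50_sh1 replicate 1, 8 without STAU1_sh2 replicate 1, 3 without control replicate 1 and 1 without DDX50_sh1 replicate 2.

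Knockdown of DDX50 against control asked the same of DDX50. Adipocyte markers fell by a median of 0.48 on the log2 scale, with 13 of 17 lower (camera adjusted p = 0.00989; adjusted p = 0.604 with an estimated correlation). The glucose transporter Slc2a4 averaged 50.4 ± 28.9 CPM (SD, n = 4) against 154 ± 80.6 (n = 2), Adig 86.6 ± 58.0 against 233 ± 165, Cidec 227 ± 62.7 against 505 ± 311 and Plin1 57.0 ± 20.8 against 115 ± 36.9. Other markers differed between the 2 shRNAs, and none passed the threshold. Fabp4 averaged 1045 ± 244 CPM with DDX50_sh1 and 452 ± 19.9 with DDX50_sh2 (n = 2 each) against 959 ± 27.5 in control, and Cebpa 79.98 ± 5.41 and 139 ± 68.1 against 119 ± 5.28. Pparg averaged 36.8 ± 3.60 and 26.9 ± 5.18 against 26.5 ± 3.16 CPM, and Adipoq 104 ± 59.0 and 284 ± 49.3 against 160 ± 148. The log2 fold change of Adipoq over both shRNAs was 0.11, but 1.66 without control replicate 2, -0.65 without control replicate 1 and -0.26 without DDX50_sh1 replicate 2, and that of Cebpa was -0.18, but 0.05 without DDX50_sh2 replicate 2. Genes of triglyceride synthesis and lipid droplets fell, with 13 of 16 lower and a median log2 fold change of -0.49; Agpat2 was at -0.83, Dgat2 at -0.98 and the seipin gene Bscl2 at -1.02 (camera adjusted p = 0.000972; adjusted p = 0.502 with an estimated correlation). Both calls ended without control replicate 2, at a camera adjusted p of 0.793 for adipocyte markers and 0.504 for triglyceride genes. In the same libraries, 16 of 17 preadipocyte and fibroblast markers were higher. The adipocyte list mean was 6.49 to 6.89 with the DDX50 shRNAs, below both control libraries at 6.91 and 7.50 (exact two-sided permutation p = 0.0667, the smallest possible, and 0.333 after Benjamini-Hochberg adjustment over 25 lists).

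Fibroblast, matrix, contractile and interferon lists rose with the DDX50 shRNAs. Preadipocyte and fibroblast markers had a median log2 fold change of 0.66; Pi16 averaged 49.5 ± 34.5 CPM (SD, n = 4) against 11.4 ± 3.65 (n = 2), Sox9 96.7 ± 32.9 against 59.0 ± 6.17 and Ly6a 185 ± 191 against 72.8 ± 41.9 (camera adjusted p = 0.00252; adjusted p = 0.502 with an estimated correlation). Extracellular matrix genes had 25 of 30 higher, with Mmp14 at a log2 fold change of 0.96, Timp2 at 1.10 and Col4a2 at 0.48 (camera adjusted p = 0.00360; adjusted p = 0.518 with an estimated correlation). Contractile genes had 17 of 18 higher, with vinculin Vcl at 1.17 and Cnn2 at 0.97 (camera adjusted p = 0.0103; adjusted p = 0.604 with an estimated correlation). Interferon-stimulated genes had 13 of 13 higher at low levels, Isg15 at 1.19 ± 0.362 against 0.351 ± 0.0743 CPM and Usp18 at 2.10 ± 0.569 against 0.748 ± 0.630 (camera adjusted p = 0.0132; adjusted p = 0.502 with an estimated correlation). Without control replicate 2 the calls of preadipocyte markers (camera adjusted p = 0.0581), contractile genes (0.0581) and interferon-stimulated genes (0.0782) ended, and without DDX50_sh2 replicate 2 those of extracellular matrix (0.156), contractile (0.275) and interferon-stimulated genes (0.156). The contractile and interferon calls also ended without control replicate 1 (0.0754 and 0.201). The interferon call further ended without DDX50_sh1 replicate 2 (0.0974), STAU1_sh2 replicate 2 (0.0601) or STAU1_sh4 replicate 1 (0.0678), and with the stricter filter (0.140).

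Ribosomal protein genes fell by the list test in DDX50 against control, although 24 of 43 were lower and the median log2 fold change was -0.05, which turned to 0.03 under another scaling. The shRNAs gave separate values: with DDX50_sh1 34 of 43 were lower (-0.47, camera adjusted p = 5.80e-05; adjusted p = 0.474 with an estimated correlation), and with DDX50_sh2 22 of 43 were higher (0.07, camera adjusted p = 0.930). Over both shRNAs Rps8 was at -1.14, Rpl14 at -1.04, Rps5 at -0.78 and Rpl13 at -0.76 (camera adjusted p = 0.0362; adjusted p = 0.697 with an estimated correlation). The direction turned without control replicate 1 (camera adjusted p = 0.835), and the call ended without DDX50_sh1 replicate 2 (0.472), DDX50_sh2 replicate 2 (0.867), STAU1_sh2 replicate 2 (0.0514), STAU1_sh4 replicate 1 (0.0678) or STAU1_sh4 replicate 2 (0.0569), and with the stricter filter (0.0562). The other 18 lists had camera adjusted p-values of 0.0556 to 0.989, fatty acid synthesis at 0.496 and adipogenic transcription factors at 0.0948 among them. No member of any called list passed the threshold adjusted over the list alone or over all genes tested. Gene by gene, edgeR called 0 of 12571 genes, with 491 at an unadjusted p under 0.05, 258 higher and 233 lower, against 629 that chance alone would give. This does not show that DDX50 has no effect, since Ddx50 itself, 3.74-fold lower, was not called. DESeq2 called 1 gene, Ddx50. The number of lists called, 7, was 3 without control replicate 2 or DDX50_sh2 replicate 2.

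**Figure D2:**
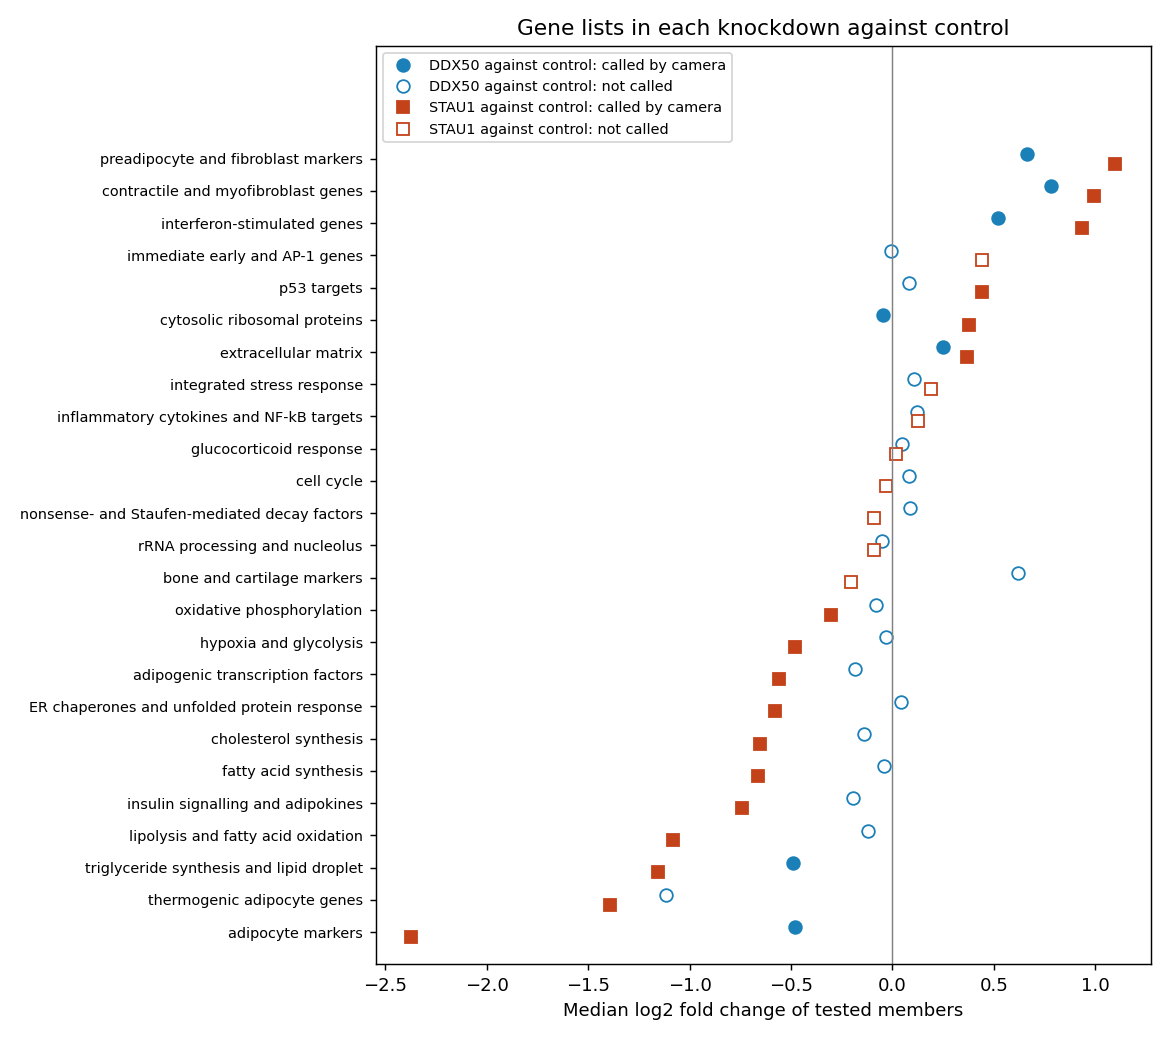
Median log2 fold change of the tested members of each gene list against control, with circles for the DDX50 shRNAs and squares for the STAU1 shRNAs, filled where camera called the list. Adipocyte markers lie lowest with the STAU1 shRNAs, at -2.38 against -0.48 with the DDX50 shRNAs, and preadipocyte and fibroblast markers highest, at 1.10 against 0.66; ribosomal protein genes with the DDX50 shRNAs lie at -0.05 and turn to 0.03 under another scaling.

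DDX50 and STAU1 knockdowns were then compared directly, without the control mean in the contrast, although the control libraries still enter the spread, filter and scaling of the fit. All 17 adipocyte markers were higher with the DDX50 shRNAs, by a median log2 fold change of 1.69, and all 17 passed the threshold adjusted over the list alone. Pparg was at 1.79, Adipoq at 2.36, Fabp4 at 1.86, Plin1 at 1.53, Cebpa at 0.95, hormone-sensitive lipase Lipe at 1.65 and Plin4 at 1.21 on the log2 scale. The camera adjusted p of the list was 2.32e-20, and the adjusted p was 0.0771 with an estimated correlation. The list means of the 4 DDX50 libraries, 6.49 to 6.89, lay above all 4 STAU1 libraries, 4.00 to 5.90 (difference 1.82, exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give, and 0.102 after Benjamini-Hochberg adjustment over 25 lists). Fatty acid synthesis was higher in 16 of 18 genes with 6 past the threshold adjusted over the list alone, Scd1 at 1.56 and Me1 at 1.64 among them (camera adjusted p = 5.15e-06; adjusted p = 0.0520 with an estimated correlation). Triglyceride and lipid droplet genes were higher in 14 of 16 with 8 past it, Lpin1 at 1.46, Agpat2 at 1.49 and Gpd1 at 1.95 (camera adjusted p = 1.52e-07; adjusted p = 0.0891 with an estimated correlation). Lipolysis and fatty acid oxidation genes were higher in 18 of 19 with 8 past it, Acadm at 1.58 (camera adjusted p = 6.60e-08; adjusted p = 0.0520 with an estimated correlation). Insulin signalling and adipokine genes were higher in 14 of 16 with 3 past it, Retn at 2.26 and Cfd at 2.23 (camera adjusted p = 1.52e-07; adjusted p = 0.0664 with an estimated correlation).

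ER chaperones, sterol and glycolytic genes were also higher with the DDX50 shRNAs than with the STAU1 shRNAs. ER chaperones had 19 of 20 higher and 4 past the threshold adjusted over the list alone, Pdia3 at a log2 fold change of 1.32, Pdia4 at 1.19, Pdia6 at 1.23 and Xbp1 at 1.67 (camera adjusted p = 1.70e-06; adjusted p = 0.0891 with an estimated correlation). Cholesterol synthesis had 17 of 23 higher and 3 past it, Cyp51 at 1.64 and Insig1 at 1.35 among them (camera adjusted p = 0.00190; adjusted p = 0.326 with an estimated correlation). Hypoxia and glycolysis had 18 of 24 higher and 0 past it, Bnip3 at 1.25 and P4ha2 at 1.33 (camera adjusted p = 0.000180; adjusted p = 0.254 with an estimated correlation). Oxidative phosphorylation had 21 of 32 higher and 1 past it, Atp5c1 at 1.35 (camera adjusted p = 0.0469; adjusted p = 0.597 with an estimated correlation). The cholesterol call ended without DDX50_sh1 replicate 2 (camera adjusted p = 0.0582). The oxidative phosphorylation call ended without control replicate 2 (0.0503), DDX50_sh1 replicate 1 (0.0780), DDX50_sh1 replicate 2 (0.0708), DDX50_sh2 replicate 1 (0.499), STAU1_sh2 replicate 2 (0.379) or STAU1_sh4 replicate 2 (0.171), with the stricter filter (0.0539) and with RLE factors (0.0591).

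Ribosomal, preadipocyte and contractile lists were lower with the DDX50 shRNAs than with the STAU1 shRNAs by the list test. Unadjusted exact two-sided permutation p-values of their list means were 0.171, 0.343 and 0.429. The ribosomal list mean differed from control by -0.34 with DDX50_sh1, 0.17 with DDX50_sh2, 0.015 with STAU1_sh2 and 0.62 with STAU1_sh4. DDX50_sh2 thus lay above STAU1_sh2. The preadipocyte mean was higher with the DDX50 shRNAs in replicate 1 (0.18) and lower in replicate 2 (-0.62). Ribosomal protein genes had 36 of 43 lower and 7 past the threshold adjusted over the list alone, Rps20 at a log2 fold change of -1.22, Rpl14 at -1.10, Rps5 at -1.04 and Rpl26 at -1.03 (camera adjusted p = 1.52e-07; adjusted p = 0.254 with an estimated correlation). Preadipocyte and fibroblast markers had 13 of 17 lower and 1 past it, Twist2 at -1.03 (camera adjusted p = 0.0432; adjusted p = 0.527 with an estimated correlation). Contractile genes had 12 of 18 lower and 0 past it, with Acta2 at -2.21 and Actn1 at -0.84 but Serpine1 at 2.28 (camera adjusted p = 0.00844; adjusted p = 0.527 with an estimated correlation). The preadipocyte call ended without control replicate 1 (camera adjusted p = 0.0689), control replicate 2 (0.0732), DDX50_sh1 replicate 2 (0.430), DDX50_sh2 replicate 1 (0.188), STAU1_sh2 replicate 2 (0.513) or STAU1_sh4 replicate 2 (0.413), and with the stricter filter (0.0539). The contractile call ended without DDX50_sh2 replicate 1 (0.220), STAU1_sh2 replicate 2 (0.271) or STAU1_sh4 replicate 2 (0.378). The other 13 lists had camera adjusted p-values of 0.0909 to 0.997.

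Gene by gene, edgeR called 1 gene in DDX50 against STAU1, Stau1, with 1505 at an unadjusted p under 0.05, 940 higher and 565 lower. Chance alone would give 629. With the replicate number as a block edgeR called 56, 48 higher and 8 lower. DESeq2 called 257, 180 higher and 77 lower. The edgeR count was 0 without DDX50_sh1 replicate 1, DDX50_sh1 replicate 2, DDX50_sh2 replicate 1, STAU1_sh2 replicate 1, STAU1_sh2 replicate 2 or STAU1_sh4 replicate 2. It was 2 without control replicate 1 or control replicate 2, 8 without DDX50_sh2 replicate 2 and 67 without STAU1_sh4 replicate 1.

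**Figure D3:**
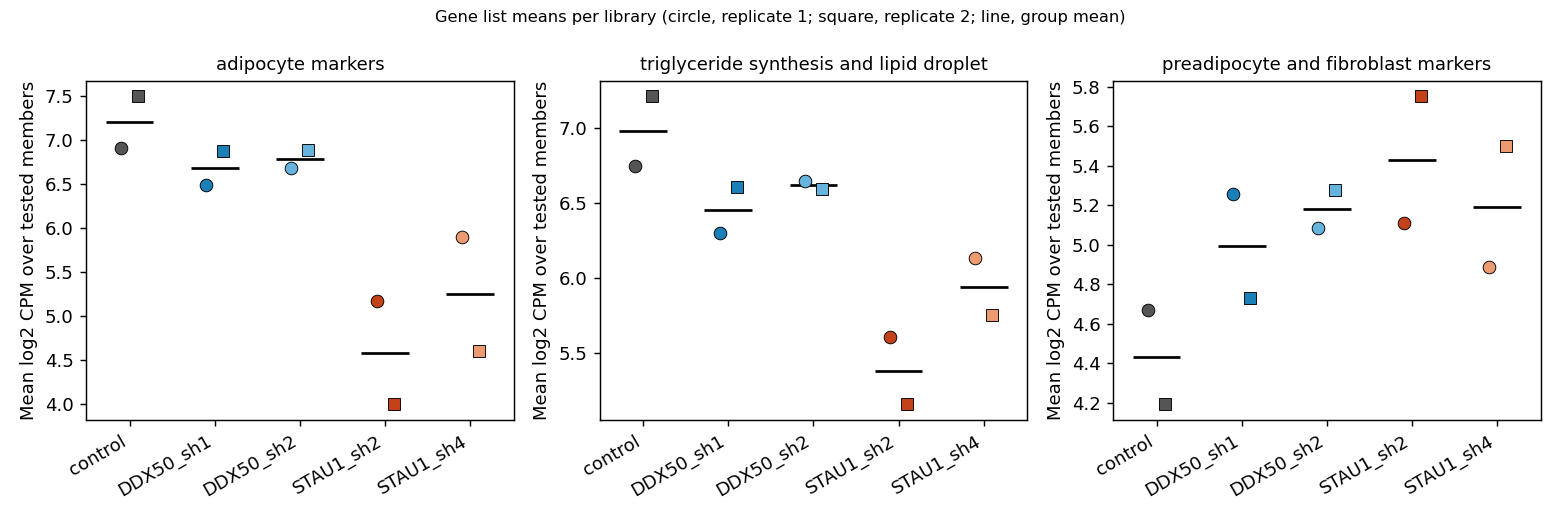
Mean log2 CPM over the tested members of the adipocyte, triglyceride and lipid droplet, and preadipocyte and fibroblast lists in each library by group, with circles for replicate 1, squares for replicate 2 and a line at the group mean. Adipocyte means lie at 4.00 to 5.90 in the 4 STAU1 shRNA libraries, below the 4 DDX50 shRNA libraries at 6.49 to 6.89 and the control libraries at 6.91 and 7.50.

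Each shRNA was also set against control by itself. Adipocyte markers fell with STAU1_sh2 in 17 of 17 genes (median log2 fold change -2.82, camera adjusted p = 8.83e-23; adjusted p = 0.0482 with an estimated correlation) and with STAU1_sh4 in 17 of 17 (-1.75, camera adjusted p = 1.35e-17; adjusted p = 0.0784 with an estimated correlation). With DDX50_sh1 they fell with 14 of 17 lower (-0.62, camera adjusted p = 0.00580; adjusted p = 0.474 with an estimated correlation), and with DDX50_sh2 12 of 17 were lower with a median of -0.49, which was not called (camera adjusted p = 0.124). Triglyceride and lipid droplet genes were called lower with each of the 4 shRNAs, at a camera adjusted p of 1.32e-13 with STAU1_sh2, 8.26e-08 with STAU1_sh4, 0.000851 with DDX50_sh1 and 0.0293 with DDX50_sh2 (adjusted p = 0.0482, 0.0784, 0.474 and 0.758 with an estimated correlation). Preadipocyte and fibroblast markers were called higher with each, at 4.79e-06, 0.000771, 0.0247 and 0.0242 in the same order (adjusted p = 0.151, 0.241, 0.474 and 0.758 with an estimated correlation). These comparisons share the same 2 control libraries, so they are not independent, and without control replicate 2 the call for both DDX50 shRNAs together ended for triglyceride and lipid droplet genes (camera adjusted p = 0.504) and for preadipocyte and fibroblast markers (0.0581). Cell cycle genes fell with STAU1_sh2, with 27 of 35 lower (median log2 fold change -0.40, camera adjusted p = 0.00414; adjusted p = 0.538 with an estimated correlation), and rose with STAU1_sh4, with 28 of 35 higher (0.37, camera adjusted p = 0.00500; adjusted p = 0.606 with an estimated correlation). The log2 fold change of Pi16 was 3.69 with STAU1_sh2 and 0.28 with STAU1_sh4. Gene by gene, edgeR called 0 genes for each shRNA, with 472 (DDX50_sh1), 922 (DDX50_sh2), 1434 (STAU1_sh2) and 1106 (STAU1_sh4) at an unadjusted p under 0.05. DESeq2 called 2, 0, 268 and 53. With the replicate number as a block edgeR called 0, 0, 61 and 0. The edgeR count for STAU1_sh2 was 36 without STAU1_sh4 replicate 1, 50 without STAU1_sh4 replicate 2 and 1 without DDX50_sh2 replicate 1 or DDX50_sh2 replicate 2.

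The fold changes of the 2 knockdowns against control were compared across genes, since the series title names cooperation of the 2 proteins. With 0 genes called in either comparison, none could be called in both, so this count holds no information on overlap. Simulated unchanged groups that share the control libraries gave 0.05 on average. At an unadjusted p under 0.05 in both, an overlap chosen after the data were examined, 132 genes were higher and 71 lower. Independent lists would give 12.2 and 14.2, and unchanged groups against shared controls gave 118 and 71.3. Over all 12571 genes, which are not independent replicates, Pearson's r was 0.66 and Spearman's rho 0.585, against 0.67 and 0.626 in the simulations. The covariance was 0.530, against a simulated 0.363. Over 6172 genes of at least 10 CPM, r was 0.57 against 0.67 and the covariance 0.147 against 0.131. With 1 control library per knockdown and none shared, an alternative chosen after the data were examined, r on log2 CPM values over all genes was 0.068 with control replicate 1 for DDX50 and replicate 2 for STAU1, and 0.0077 the other way round. Over genes of at least 10 CPM it was 0.19 and 0.014, and the highest of the simulations was 0.034 and 0.021. With 1 control library shared by both knockdowns, r was 0.83 without control replicate 1 and 0.81 without control replicate 2, against 0.84 in simulated unchanged groups for each. Between the shRNAs of one target, r was 0.60 for STAU1 (simulated 0.50; covariance 0.763 against 0.366) and 0.45 for DDX50 (simulated 0.51; covariance 0.395 against 0.362). Over genes of at least 10 CPM, r was 0.60 for STAU1 (simulated 0.50; covariance 0.285 against 0.131) and 0.20 for DDX50 (simulated 0.50; covariance 0.0573 against 0.131), so for DDX50 the covariance was above the simulated mean over all genes and below it here. With edgeR 0 genes were called for each shRNA, so none could be called in both shRNAs of a target. DESeq2 called 30 in both STAU1 shRNAs in the same direction.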

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

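Tests on the share of differentiated cells, scaling, shared controls and the single control library were chosen after the results were seen. The 2 shRNAs of a target differed from each other in 11 gene lists by the direct camera test, and none of these differences held with an estimated correlation. With STAU1_sh2 against STAU1_sh4, lists were lower for cell cycle (32 of 35 genes lower, median log2 fold change -0.75, camera adjusted p = 5.00e-09), cytosolic ribosomal proteins (37 of 43, -0.67, 1.34e-08), rRNA processing and nucleolus (41 of 44, -0.56, 1.20e-07) and oxidative phosphorylation (29 of 32, -0.40, 7.43e-05). With an estimated correlation the adjusted p was 0.440 for each of these lists. Triglyceride and lipid droplet genes were lower in 16 of 16 (-0.61, camera adjusted p = 0.00118; adjusted p = 0.440 with an estimated correlation) and adipocyte markers in 17 of 17 (-0.65, 0.00157; adjusted p = 0.554 with an estimated correlation). Higher with STAU1_sh2 were extracellular matrix genes (22 of 30, 0.24, camera adjusted p = 0.00229), immediate early genes (17 of 23, 0.42, 0.00361) and contractile genes (15 of 18, 0.53, 0.0121), with an adjusted p of 0.440, 0.393 and 0.581 with an estimated correlation. With DDX50_sh1 against DDX50_sh2, hypoxia and glycolysis genes were higher in 21 of 24 (0.60, camera adjusted p = 0.00389; adjusted p = 0.891 with an estimated correlation) and ribosomal protein genes lower in 28 of 43 (-0.42, 0.0112; adjusted p = 0.927 with an estimated correlation). Gene by gene, edgeR called 0 genes in both contrasts, with 993 and 1131 at an unadjusted p under 0.05, and DESeq2 called 34 and 16. In STAU1_sh2 against STAU1_sh4 edgeR called 1 gene without DDX50_sh2 replicate 1, DDX50_sh2 replicate 2 or STAU1_sh4 replicate 1.

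Adipocyte markers were lower with the STAU1 shRNAs in all 17 tested genes. The tables argue against the choice of scaling as the whole cause. The median log2 fold change lay between -2.41 and -2.32 under TMM, RLE, upper quartile and no scaling. With TMM factors of only 0.911 to 1.18, no large shift was open to this test. They also argue against depth: with every library thinned to 8693588 counts the median was -2.34 and the camera adjusted p 1.40e-23. A lower share of differentiated cells stays open, since 82.4% of the 17 tested preadipocyte and fibroblast markers were higher, the most abundant of them S100a4 (1589 ± 1176 against 593 ± 47.2 CPM) and Vim (652 ± 129 against 559 ± 18.6), and 1 of the 17, Sox9, is in another list. A change of adipocyte transcripts within each cell, which the shRNAs could also cause, was not tested apart from it.

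Fold changes of the 2 knockdowns correlated across genes, and the control libraries they share may account for this. Over genes of at least 10 CPM the covariance was 0.147 and the highest of 20 simulations 0.138, while the covariance that sharing the 2 libraries of a group would add, taken from the variance of their difference, was 0.105 for control, 0.0844 for DDX50_sh1, 0.163 for DDX50_sh2, 0.122 for STAU1_sh2 and 0.206 for STAU1_sh4. A first form of this test used the control value of 0.105 alone and excluded shared controls; it was widened to the 5 groups after that outcome, since the values of single pairs of libraries differ this much. With 1 control library per knockdown and none shared, the covariance on log2 CPM values was 0.0601 with control replicate 1 for DDX50 (highest of 20 simulations 0.0114) and 0.00572 the other way round (0.00701), against 0.197 and 0.289 with control replicate 1 or 2 shared. The 2 assignments disagree, and deviations common to libraries of the same number would lower both values, so shared controls and a shared effect cannot be told apart with 2 control libraries.

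Adipocyte markers were lower with the DDX50 shRNAs in 13 of 17 genes by the list test. The call may rest on 1 control library, since the camera adjusted p was 0.793 without control replicate 2, which has the higher adipocyte mean (7.50 against 6.91), and 0.00212 without control replicate 1. Without control replicate 2, DDX50 libraries of both numbers were set against a control of replicate 1 alone. An effect of DDX50 on these genes stays open, since the 4 DDX50 libraries lay below both control libraries. Against the control library of the same number, the list mean differed by -0.33 in replicate 1 and -0.62 in replicate 2. The list call also held with the replicate number as a block.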

How the results depend on the processing

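Scaling of lists, thinning, the overlap at an unadjusted p and 1 control library per knockdown were added after the data were examined. Of 299 comparisons of a main count, correlation or adipocyte list with an alternative, 233 kept their size or side. Of 3148 for named genes and other lists, 2829 did and 319 did not, 15 of them changing direction. A count of 0 that stayed 0 was scored as kept, as was an uncalled gene that stayed uncalled with its sign. Most main counts were 0, so these totals say little about robustness. The gene count of DDX50 against STAU1 was kept in 1 of 17 alternatives. Unless construction is named, the cause of a change was not tested. Without a low-count filter, which tests more genes, the calls were 4 for DDX50 against control, 276 for STAU1, 280 for DDX50 against STAU1, 9 for DDX50_sh1, 68 for DDX50_sh2, 280 for STAU1_sh2, 126 for STAU1_sh4, 190 between DDX50 shRNAs and 68 between STAU1 shRNAs, with 1 gene in both DDX50 shRNAs, 59 in both STAU1 shRNAs and 3 in both knockdowns. RLE factors, the stricter filter and the groups compared alone gave 0 for DDX50 against STAU1, and the last gave 1 for STAU1_sh2. DESeq2 gave 1, 217 and 257 for the 3 main comparisons, 2 for DDX50_sh1, 268 for STAU1_sh2, 53 for STAU1_sh4, 16 and 34 between shRNAs and 30 in both STAU1 shRNAs. The main edgeR counts were 0, 0 and 1, and 0 elsewhere. With an estimated correlation 0, 5 and 0 lists were called, with the adipocyte list at an adjusted p of 0.604 for DDX50 and 0.0771 for DDX50 against STAU1; fry called 0, 8 and 6, with 0.828 for DDX50; camera called 7, 17 and 12. Over all alternatives the adipocyte adjusted p ran from 0.00163 to 0.828 for DDX50, 7.19e-27 to 0.0431 for STAU1 and 8.71e-26 to 0.0771 for DDX50 against STAU1.

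The replicate number as a block gave 42 genes for STAU1, 56 for DDX50 against STAU1 and 61 for STAU1_sh2, turned Ddx21 with STAU1 to -0.046, ended the p53 call (camera adjusted p = 0.0607) and that of oxidative phosphorylation in DDX50 against STAU1 (0.0558), and ended no other list call. Deviations of same-numbered libraries correlated at -0.0963 to 0.46 over 10 pairs of groups, 8 of them over 0.1. Outside their group, 9 of 10 libraries correlated best with one of their own number. Only 1 library had its best match overall in its own group. On the first principal component of the 2000 most variable genes (23.4% of the variance), replicate 1 lay below replicate 2 in every group. Pairs of control with another group were at 0.101 to 0.319. The main fit was set without a block before the data were examined, and not all pairs passed 0.1. Its spread therefore includes any structure shared by number, and the permutation tests did not pair libraries by number.

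Leaving out 1 library gave 0 to 106 genes for STAU1 (106 without STAU1_sh4 replicate 1), 0 to 67 for DDX50 against STAU1, 0 to 50 for STAU1_sh2, 0 to 1 between STAU1 shRNAs, 3 to 9 lists for DDX50, 0.00163 to 0.793 for its adipocyte list and a correlation of 0.60 to 0.83. With 1 control library per knockdown and none shared, the correlation was 0.068 with replicate 1 for DDX50 and 0.0077 with replicate 2 for DDX50. Log2 fold changes whose sign turned ran, over the libraries left out, from -0.55 to 0.074 for Ddx21 with DDX50 (0.074 without control replicate 1), from -0.56 to 0.16 for Ddx21 in DDX50 against STAU1 (0.16 without STAU1_sh4 replicate 1) and from -0.44 to 0.37 for Ddx21 with STAU1, where the value was -0.25 without control replicate 2, -0.26 without STAU1_sh2 replicate 1 and -0.44 without STAU1_sh4 replicate 1. Adipoq with DDX50 ran from -0.65 (without control replicate 1) to 1.66 and was -0.26 without DDX50_sh1 replicate 2. Cebpa with DDX50 ran from -0.48 to 0.048 (without DDX50_sh2 replicate 2), and Ddx50 with STAU1 from -0.77 to 0.042 (without control replicate 1). Without control replicate 2, Stau1 with DDX50 was -0.12 (range -0.12 to 0.66), Ebf2 with STAU1 0.63 (-1.21 to 0.63) and Sdf2l1 with STAU1 0.27 (-1.87 to 0.27). List directions turned without control replicate 1 for ribosomal proteins with DDX50 (adjusted p 0.835, range 0.000257 to 0.867) and p53 targets with STAU1 (0.813, range 0.000387 to 0.813). The median log2 fold change of all genes lay between -0.047 and 0.11 in the 3 main comparisons under TMM, RLE, upper quartile and no scaling. In simulated counts 2-fold changes were recovered in 0 to 3.5% of genes, so changes of that size in single genes would mostly be missed with 2 libraries per group.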

Other observations

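Several genes outside the fixed lists stood at the top of STAU1 against control, and were chosen after their values were seen. Mrap, an accessory protein of melanocortin receptors, averaged 20.1 ± 8.90 CPM (SD, n = 4) with the STAU1 shRNAs, 70.4 ± 30.8 with the DDX50 shRNAs and 182 ± 106 (n = 2) in control, a log2 fold change of -3.27 with STAU1 (edgeR adjusted p = 0.0503). Adtrp, at 1.88 ± 1.04, 5.83 ± 1.87 and 19.4 ± 3.07 CPM, the adaptor Sh2b2, at 5.33 ± 2.27, 16.4 ± 2.44 and 27.4 ± 2.56, and the phosphatase Dusp4, at 3.25 ± 1.11, 10.1 ± 3.81 and 18.2 ± 0.107, had the same adjusted p and the same order of means. Hcar2, a receptor for hydroxybutyrate that is abundant in adipocytes, had a log2 fold change of -2.88 (adjusted p = 0.0730). Smad6, an inhibitor of BMP signalling, went the other way, at 11.7 ± 2.46 CPM with the STAU1 shRNAs, 4.94 ± 0.667 with the DDX50 shRNAs and 1.85 ± 0.0890 in control (log2 fold change 2.65, adjusted p = 0.0868). None of these passed the threshold with edgeR.

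The most abundant gene in the table had no symbol: ENSMUSG00000119584.1, on chromosome 17 from 40157244 to 40159092, held 6.03 to 11.1% of the counts of each library. The mitochondrial ribosomal RNA mt-Rnr2 held 2.30 to 7.37%, and all mitochondrial genes 3.22 to 8.29%. The share of all mitochondrial genes was 6.72 to 8.29% in the 4 DDX50 libraries, above 5.70 and 3.62% in control. In the STAU1 libraries it was 3.22 to 6.46%. Whether this bears on the changes with the DDX50 shRNAs was not tested. Among mitochondrial protein genes over 200 bases, 5 (mt-Co2, mt-Atp8, mt-Co3, mt-Nd3 and mt-Nd4l) had 0 counts in all 10 libraries, and mt-Atp6 had 3 counts in 1 library, while mt-Co1 had 2841 to 8238. Levels of such genes were not interpreted.

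The 8 knockdown libraries can be divided into 4 and 4 in 35 ways, and chance was not excluded for the number of genes or lists called in DDX50 against STAU1. With 3 groups by target the real division gave 1 gene, and 2 of the 35 divisions gave as many. The highest other division gave 541 genes. It put both DDX50_sh1 libraries with replicate 1 of STAU1_sh2 and of STAU1_sh4. These libraries lay at -31.3, -7.6, -6.4 and -20.4 on the first principal component, and the rest of the knockdown libraries at 5.7 to 47.8. A count this high thus follows the main axis of variation between samples, whose cause was not tested. The real division gave 11 lists, and 7 of 35 gave as many, with 14 in the highest other. Dividing by replicate number gave 0 genes and 7 lists, with 992 genes at an unadjusted p under 0.05. The real division gave 1281 such genes, and chance alone would give 629. Of the 35 divisions, 5 gave as many, with 2787 in the highest other. For the adipocyte list by itself, the mean log2 difference of 1.72 in the real division was the largest of the 35, the next being 1.28. The camera adjusted p of this list was 1.63e-20 in the real division and 7.48e-22 in the division with 1.28. That division put DDX50_sh1 replicate 1 with both STAU1_sh2 libraries and STAU1_sh4 replicate 2. Camera also called the list in some divisions with 2 libraries of each target on each side, though not in most. The lowest adjusted p among these was 3.43e-05.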
